A study of Mus musculus with 8 samples.

How the data were processed

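Total liver RNA of 4 pools was hybridised to 8 Affymetrix arrays. Per the labels, 5 µg of pooled total RNA was reverse transcribed and amplified by in vitro transcription with biotin labelling. The mice were female BALB/c, 10 to 12 weeks old. Stress sessions of 2 h combined restraint in a ventilated tube with randomised ultrasound between 19 and 25 kHz, in the morning and the afternoon, with a single session on the last morning. The deposited values are signal intensities on a linear scale, 1 per probe set and array, and GCOS is the software named in the submitters' processing notes, with no version given there. The scaling target and the detection settings are not given in the sources used here. The 2% trimmed mean over all probe sets was 150.1 on each array, so the arrays had been brought to a common scale before deposit. Signals ran from 0.163 to 30330, and no array shared more than 1 identical value with another.

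Of 22690 deposited probe sets, 64 control probe sets were left out. Gene names came from the platform annotation by way of Entrez identifiers matched to RefSeq gene names of the GRCm38.p6 assembly. Of the remaining 22626 probe sets, 20380 had 1 gene symbol, 691 had several and 1555 had none, and a name was used only where there was 1. Of those, 20364 matched by Entrez identifier. No coordinates were used, since no genome build is named in the sources used here. Some of the genes fixed in advance are not reported here.

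Signals were taken to log2 with no added constant, since none was at or below 0. Probe sets with a mean log2 signal over all arrays at or below the 40th percentile (a signal of 26.1) were left out, which kept 13575 probe sets, 12473 with a name, for 8202 genes. The 2 arrays of a pool were averaged. Stressed and control pools were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the 13575 probe sets, and called at an adjusted p under 0.05. The residual degrees of freedom were 2 and the prior degrees of freedom 8.06. A split of 2 against 2 pools allows no exact test below 0.05, so the moderated test carries the comparison. For a gene with several probe sets the brightest by mean log2 signal stood for the gene. Of the genes that changed, 26 had several probe sets tested, and in none of them did probe sets with an unadjusted p under 0.05 go opposite ways. Figures were drawn with matplotlib 3.10.9.

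Before the data were examined, 40 gene lists were fixed, 27 of pathways and 13 of cell types. They named 694 genes, of which 606 were on the array. The 32 lists with at least 5 genes past the filter were tested with limma's camera (preset inter-gene correlation 0.01) with Benjamini-Hochberg adjustment over the lists. Genes were also counted with adjustment over the list alone. Of the 15 lists that passed, 0 did so with camera and an estimated correlation, where 5 of the 32 lists had an unadjusted p under 0.05, and 0 had one with the block as well. That version of the test has the residual degrees of freedom of the fit, 2 without the block and 1 with it. It therefore has little power, so a list that fails it is not shown to be unchanged. The 8 lists under 5 genes were not tested. They were T cells (2 genes), B cells (3), NK cells (2), erythroid cells (3), cholangiocytes (2), pancreatic acini (4), skeletal muscle (0) and adipocytes (1).

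The rule for the genes named in the report was fixed at the same time. It took the 12 genes with the largest rise and the 12 with the largest fall among those passing the test with the arrays of both experiments separated. For a direction in which fewer than 5 passed, it took the 10 with the lowest p in that direction that met the array rule. It added up to 4 genes with the largest change from each list that passed, and 19 genes named in advance. Other genes, among them list members named beside a count and Fabp5, Il6ra, Cxcl9, Igtp, Cd74 and Trp53inp1, were chosen after their values were seen.

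The experiment number was shared by a stressed and a control pool. The series design describes each experiment as holding both groups, so the number pairs the pools. Deviations from the group means correlated at 0.243 between pools of the same number. The value of -0.243 between pools of different numbers follows from it by construction with 2 pools per group. The fit without the block was fixed as the main one, and the block was run as an alternative. With the block, 1 residual degree of freedom was left and the prior degrees of freedom were infinite, so its p-values rest on the fitted mean-variance trend. Pairs of arrays of the same pool correlated with a median of 0.910, those of the same experiment and other group of 0.891, and those of the same group and other experiment of 0.886. The signal of the 5' probe set of the spiked-in Thr control transcript ran from 4424 to 5894 on the arrays of experiment 1 and from 898 to 1183 on those of experiment 2. The ratio of 3' to 5' beta-actin signal ran from 1.45 to 1.91 on the arrays of experiment 1 and from 1.995 to 3.16 on those of experiment 2. It was highest on the second array of control pool 2.

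The alternatives fixed in advance were quantile normalization, median centring, log2 of the signal plus 32, no filter and a filter at the 60th percentile, no mean-variance trend, the block, all 8 arrays with the pool as a random block, each technical array alone, each pool left out, a fold threshold of 2, an estimated correlation between genes and the mean over the probe sets of a gene. Leaving out a pool puts 1 pool in an arm, which is assumed to vary like the other group. Added after seeing the data were control pool 2 by its first array alone, and the block together with an estimated correlation. Data were simulated with the smoothed spread of these pools at each signal level, independent probe sets and no difference between experiments. On them the fit recovered 38 of 100 probe sets changed by 1 and 77 of 100 changed by 2 on the log2 scale, with 7 false calls among 13575 probe sets. The block recovered 45 and 77, with 12 false calls. Of 10 simulated lists shifted by 1, all 10 were called, and of 40 unshifted lists 0 were. That shift exceeds the median change of every list that passed but the glucocorticoid list. The simulation builds in the mean-variance trend and independent genes, so it tests neither assumption.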

Results

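Liver RNA was measured on 8 Affymetrix arrays from female BALB/c mice that had either been exposed to repeated combined acoustic and restraint stress for 4.5 days or left untreated. The study was run as 2 separate experiments, each with a stressed and a control group. The liver RNA of 8 or 9 mice of each group was pooled, and each of the 4 pools was hybridised to 2 arrays. The replicate is the pool, so n = 2 pools per group, and each pool value is the mean of its 2 arrays on the log2 scale. The limma p-values of single probe sets therefore rest on 2 pools per group, with 2 residual degrees of freedom against 8.06 prior ones. Most of the weight in each variance thus comes from the mean-variance trend over all probe sets, and the number of pools limits the precision. The camera p-values with the preset correlation instead set the genes of a list against all other genes. They rest mainly on the spread between genes and do not measure the spread between pools. The 2% trimmed mean signal was 150.1 on every array and the median signal ran from 42.6 to 57.3. Stressed mice were kept outside the incubator in which the control mice stayed, so housing differed between the groups along with the stress sessions. All log2 changes are stressed minus control, with the standard error (SE) of the limma fit.

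The comparison of stressed with control liver asks which transcripts changed in abundance over the days of repeated stress, with tissue taken after the ninth session. Saa2 and Saa1, which encode the inducible serum amyloid A proteins, rose by 4.93 (SE 0.19) and 4.58 (SE 0.22), from mean signals of 168 and 312 in the control pools to 5097 and 7480 in the stressed pools. Lcn2, which encodes the iron-siderophore-binding protein lipocalin 2, rose by 4.89 (SE 0.26), from 93.5 to 2764. The metallothionein genes Mt2 and Mt1, whose products bind zinc and copper, rose by 4.00 (SE 0.46) and 2.75 (SE 0.33). Igfbp1, which encodes a binding protein of insulin-like growth factors, rose by 3.45 (SE 0.21), and Lpin1, which encodes the phosphatidate phosphatase lipin 1, rose by 3.35 (SE 0.26). Nnmt, which encodes nicotinamide N-methyltransferase, rose by 3.03 (SE 0.31). With limma and Benjamini-Hochberg adjustment, the adjusted p of these 8 genes lay between 2.1e-06 (Saa2) and 0.00585 (Mt1). These 8 also stayed below 0.05 with any 1 of the 4 pools left out, the highest adjusted p being 0.0445 (Mt1 and Nnmt without control pool 1). Without the mean-variance trend in the variance model their adjusted p ran from 0.0878 (Saa2) to 0.743 (Mt1).

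**Figure D1:**
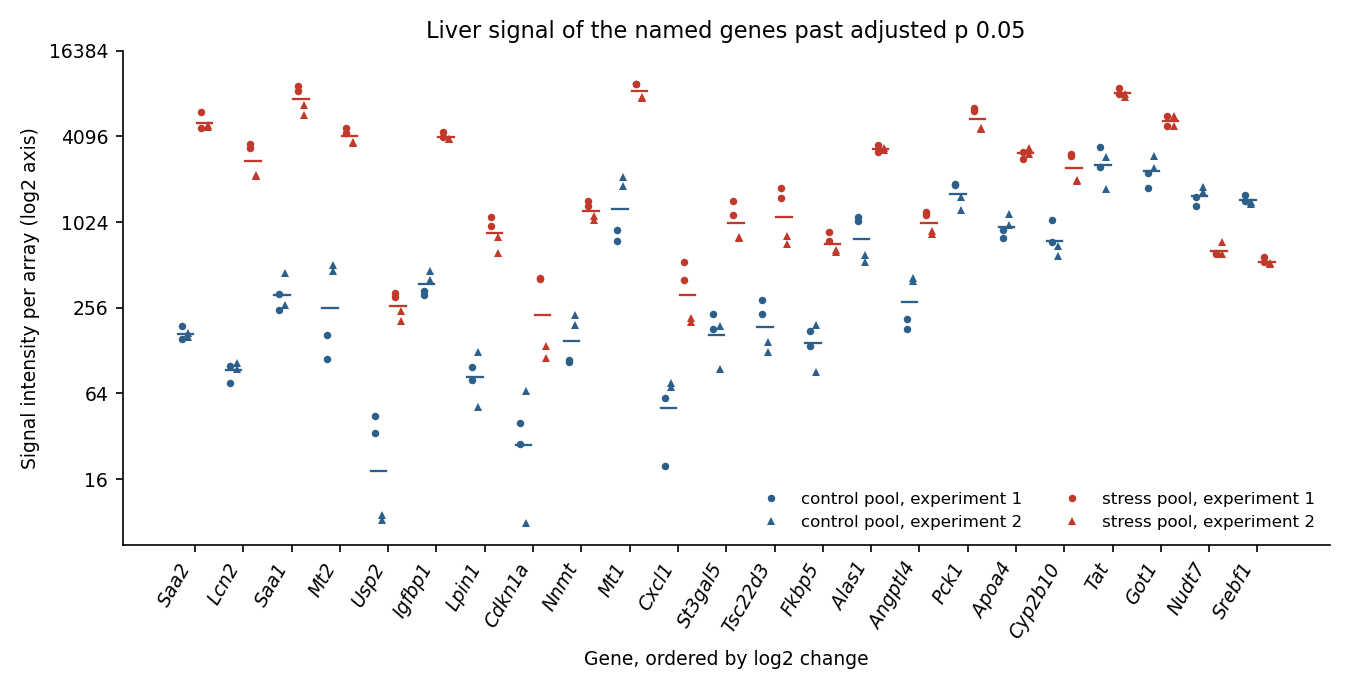
Signal intensity on each array (log2 axis) of the 23 named genes with an adjusted p below 0.05, with control pools in blue, stressed pools in red, experiment 1 as circles, experiment 2 as triangles and the group mean as a bar. Saa2 had mean signals of 5097 in the stressed and 168 in the control pools, and Srebf1 of 539 and 1454.

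Over all genes, 57 of 13575 probe sets changed with limma, 55 higher and 2 lower in stressed liver, and they named 44 genes. In all 57, both arrays of the stressed pool lay on the same side of both arrays of the control pool in each experiment. At an unadjusted p under 0.05 there were 627 probe sets, 341 higher and 286 lower. With the experiment as a block, 460 probe sets passed, 289 higher and 171 lower, and all 57 were among them. Without the mean-variance trend 0 passed with limma, with 676 at an unadjusted p under 0.05, all 57 among them, and the smallest adjusted p was 0.0878. The count was 161 without stressed pool 2, 15 without control pool 1 and 13 without control pool 2. Over all alternatives the adjusted p of the 23 named genes that passed ran from 1.1e-243 (Saa2 with the block) to 0.833 (Got1 without the trend), and the highest value of each gene was the one without the trend.

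Among the other named rises, Usp2, which encodes a ubiquitin-specific protease, rose by 3.86 (SE 0.62, adjusted p = 0.0278) from a mean control signal of 18.3, which lay below the signal of 26.1 that the filter asked of the mean over all arrays. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose by 3.04 (SE 0.53, adjusted p = 0.0430), with signals of 66.5 and 7.85 on the 2 arrays of control pool 2. With the first of these arrays alone, a choice made after seeing the data, its change was 2.27 (adjusted p = 0.290). Cxcl1, a neutrophil-attracting chemokine, rose by 2.64 (SE 0.45, adjusted p = 0.0409), and St3gal5, the sialyltransferase that makes ganglioside GM3, rose by 2.61 (SE 0.30, adjusted p = 0.00376). Each of these 4 calls was lost with a control pool left out. Without control pool 2 the adjusted p was 0.0715 for Usp2, 0.554 for Cdkn1a and 0.120 for St3gal5, and without control pool 1 it was 0.416 for Cxcl1, 0.262 for Cdkn1a and 0.0552 for St3gal5. Cdkn1a also had an adjusted p of 0.257 without stressed pool 1, and Cxcl1 of 0.136 without control pool 2. Among the named rises, another probe set did not pass for Usp2 (3.37), Cdkn1a (2.38), Mt1 (2.22), St3gal5 (1.78), Alas1 (0.96) and Tsc22d3 (2.09 and -0.26).

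Among the lists that were tested, the glucocorticoid-induced genes had the highest median change. Of its 21 measured genes, 11 rose, none fell and 10 did not pass over all genes, while 17 rose adjusted over the list alone. All 21 had a positive change, with a median of 1.73. Besides Lcn2, Mt1, Mt2, Igfbp1, Lpin1, Cdkn1a, Tat, Angptl4 and Cebpb, the list held Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor and rose by 2.32 (SE 0.24, adjusted p = 0.00262), and Tsc22d3, which encodes the leucine zipper protein GILZ and rose by 2.57 (SE 0.39, adjusted p = 0.0206). Per1, a clock gene that glucocorticoids induce in many tissues, was at 0.27 (SE 0.90, adjusted p = 1.00) and at a mean control signal of 24.8. The camera test of the list gave an adjusted p of 1.8e-53 with a preset correlation between genes, and adjusted p = 0.282 with an estimated correlation. The estimated version has 2 residual degrees of freedom, here and for every list below, and so has little power. Without control pool 2 the adjusted p was 0.0752 for Fkbp5 and 0.371 for Tsc22d3, and without control pool 1 it was 0.0552 and 0.104.

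The acute-phase list had 26 measured genes, of which 4 rose, none fell and 22 did not pass over all genes, and 12 rose adjusted over the list alone. Il6ra, which encodes the interleukin 6 receptor, was the fourth beside Saa1, Saa2 and Lcn2, at 1.75 (SE 0.25, adjusted p = 0.0180). Orm3, which encodes an orosomucoid, was at 2.14 (SE 0.56, adjusted p = 0.335) and passed with the experiment as a block (adjusted p = 0.00193). But its signals were low, 10.7 and 20.7 on the arrays of control pool 1 and 94.5 and 15.3 on those of control pool 2. The second array of stressed pool 2, at 56.4, lay below the 94.5, so the arrays of that experiment overlapped. The median change of the list was 0.53, with a camera adjusted p of 1.5e-25, and adjusted p = 0.336 with an estimated correlation. Lcn2 was a member of both this and the glucocorticoid list. Saa4 of this list and Errfi1 of the glucocorticoid list did not pass by their brightest probe sets, but another probe set of each rose, by 1.35 (adjusted p = 0.0335) and 1.69 (adjusted p = 0.0305). Il6ra, Saa4 and Errfi1 were picked for mention after their values were seen.

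Lists of gluconeogenesis, amino acid catabolism and the urea cycle also passed with camera, as higher, but had adjusted p = 0.282, adjusted p = 0.282 and adjusted p = 0.336 with an estimated correlation. Pck1, which encodes the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis, rose by 1.75 (SE 0.22, adjusted p = 0.00710), and Tat, which encodes tyrosine aminotransferase, rose by 1.68 (SE 0.19, adjusted p = 0.00376). Got1, the cytosolic aspartate aminotransferase gene, rose by 1.17 (SE 0.19, adjusted p = 0.0336). Got1 counted in both the gluconeogenesis and the amino acid list, and Tat in the amino acid and the glucocorticoid list. Cdkn1a and Angptl4 of the glucocorticoid list likewise counted in the growth arrest and the lipoprotein list, so these lists are not independent. Of the 14 gluconeogenesis genes 2 rose and 12 did not pass, and 3 rose adjusted over the list alone (median 0.47, camera adjusted p = 7.9e-08). G6pc, the catalytic subunit gene of glucose-6-phosphatase, was at 0.84 (SE 0.38, adjusted p = 1.00), and Slc37a4, the gene of the glucose-6-phosphate transporter, at 1.00 (SE 0.19, adjusted p = 0.0693). With the experiment as a block both passed, at 1.4e-07 and 4.6e-11. Of the 30 genes of amino acid catabolism 2 rose and 28 did not pass, and 6 rose adjusted over the list alone (median 0.27, camera adjusted p = 3.8e-09). Of the 7 urea cycle genes none passed over all genes and 3 rose adjusted over the list alone, Asl, Slc25a15 and Arg1, at 1.02, 0.70 and 0.53, and these 3 passed with the block, at 1.1e-11, 1.3e-05 and 0.00625 (median 0.35, camera adjusted p = 6.4e-06). Without control pool 2 the adjusted p was 0.204 for Pck1, 0.100 for Tat and 0.136 for Got1, and without control pool 1 it was 0.0770 for Pck1 and 0.360 for Got1.

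Cdkn1a and Trp53inp1, a p53-inducible gene that rose by 1.99 (SE 0.24, adjusted p = 0.00466), were the growth arrest genes that passed. In the list of growth arrest and p53 targets, 2 of 15 genes rose, 13 did not pass and 5 rose adjusted over the list alone (median 0.35, camera adjusted p = 3.6e-07, adjusted p = 0.338 with an estimated correlation). These 5 were Cdkn1a, Trp53inp1, Gadd45b, Gadd45g and Plk3. Gadd45g, a growth arrest and DNA damage-inducible gene, was at 2.92 (SE 0.61, adjusted p = 0.117) and passed with the block (adjusted p = 2.4e-34). The brightest probe set of its relative Gadd45b was at 2.47 (SE 0.44, adjusted p = 0.0511, with the block 6.0e-11), while another probe set of Gadd45b rose by 3.40 (SE 0.40, adjusted p = 0.00455). Of 26 cell cycle genes on the array only 8 lay above the filter. All 8 had a negative change, with a median of -0.97, but none passed over all genes and 1 fell adjusted over the list alone. Several were dim, such as Aurka, with mean signals of 18.9 in the stressed and 51.2 in the control pools, and Mcm4, with 25.2 and 70.2. With no filter the median was -0.65. That gene was Ccnd1, which encodes cyclin D1, at -1.15 (SE 0.27, adjusted p = 0.233, with the block 1.6e-05). The camera adjusted p of the cell cycle list was 5.1e-05, and adjusted p = 0.298 with an estimated correlation.

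Only 2 genes passed the test as lower in stressed liver. Srebf1, which encodes the lipogenic transcription factor SREBP-1, fell by 1.43 (SE 0.20, adjusted p = 0.0119), from 1454 to 539. Nudt7, which encodes a peroxisomal coenzyme A diphosphatase, fell by 1.29 (SE 0.20, adjusted p = 0.0248), but another Nudt7 probe set was at -0.21 (SE 0.34, adjusted p = 1.00). Without control pool 1 the adjusted p was 0.215 for Srebf1 and 0.185 for Nudt7, and without control pool 2 it was 0.204 and 0.435. The 8 genes that came next by p did not pass. Lifr, a subunit gene of the leukaemia inhibitory factor receptor, was at -1.23 (SE 0.24, adjusted p = 0.0755), Osgin1 at -2.02 (SE 0.43, adjusted p = 0.123) and Tmsb10, which encodes thymosin beta 10, at -1.04 (SE 0.22, adjusted p = 0.122). Mcm10, Psmb9, Ccnd1, Mid1ip1 and Ifi47 lay between -1.06 and -1.24, with adjusted p from 0.126 to 0.288. With the experiment as a block all 8 passed, with adjusted p from 1.0e-26 (Osgin1) to 1.6e-05 (Ccnd1). Other probe sets did not pass with the block for Lifr (-0.46 and 0.65, with the block 0.254 and 0.881) and Tmsb10 (-0.88 and -0.67, with the block 0.105 and 0.585). Igf1, the insulin-like growth factor 1 gene, was at -0.47 (SE 0.19, adjusted p = 0.938, with the block 0.0167), and its other probe sets were at -0.49 and -0.53 (with the block 0.0614 and 0.00430).

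The interferon and antigen presentation lists passed with camera, as lower, with no gene passing over all genes. The camera adjusted p was 5.6e-10 for the interferon list and 1.4e-05 for the antigen presentation list, but adjusted p = 0.367 and adjusted p = 0.464 with an estimated correlation. Of 21 interferon response genes, 20 had a negative change (median -0.48), and 4 fell adjusted over the list alone, Psmb9, Gbp2, Cxcl9 and Igtp. Psmb9, which encodes an immunoproteasome subunit, was at -1.24 (SE 0.27, adjusted p = 0.143, with the block 3.7e-06), and Gbp2, a guanylate-binding protein gene, at -1.19 (SE 0.34, adjusted p = 0.405, with the block 0.0255). Of 11 antigen presentation genes, 10 had a negative change (median -0.83), and 4 fell adjusted over the list alone, H2-Ab1, H2-Aa, Cd74 and Tap1. Of these 8 genes only Tap1 did not pass over all genes with the block (adjusted p = 0.0804). The 10 negative antigen presentation genes included values near 0, those of the MHC class I genes H2-K1 (-0.09) and H2-D1 (-0.14) and of Tapbp (-0.09). B2m was at 0.06. The MHC class II genes H2-Ab1 and H2-Aa were at -1.61 (SE 0.41, adjusted p = 0.300, with the block 0.000121) and -1.20 (SE 0.35, adjusted p = 0.430, with the block 1.7e-06). Another Gbp2 probe set was at -1.03 (with the block 0.414). The H2-Ab1 value leaned on 1 array of stressed pool 2, with a signal of 12.2 against 97.3 on its duplicate, and 2 other H2-Ab1 probe sets were at -0.51 and -0.70 (with the block 0.792 and 0.464). Another H2-Aa probe set was at -0.77 (with the block 0.0876). The Kupffer cell and macrophage markers moved in the same direction, with 11 of 12 negative, a median of -0.28 and none passing over all genes or over the list alone (camera adjusted p = 0.00644, adjusted p = 0.484 with an estimated correlation). Among these markers Vsig4 had mean signals of 497 in the stressed and 619 in the control pools, and Cd5l of 303 and 405. The Kupffer list had an adjusted p of 0.264 without stressed pool 2 and 0.300 without control pool 1. Of 13 extracellular matrix genes none passed in either count (median -0.38, camera adjusted p = 0.0220, adjusted p = 0.498 with an estimated correlation). The matrix list had an adjusted p of 0.548 without stressed pool 1, 0.201 without control pool 2 and 0.197 with technical array 1 alone.

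**Figure D2:**
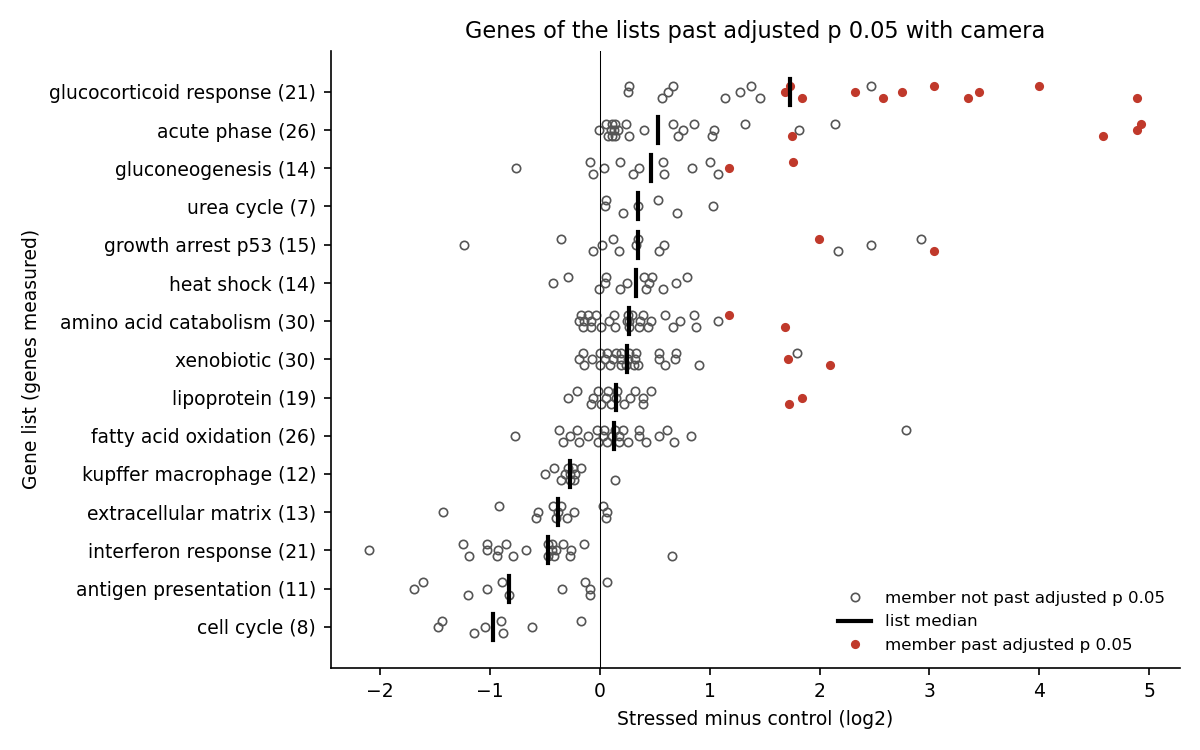
Stressed minus control log2 change (horizontal axis) of each measured gene in the 15 gene lists past an adjusted p of 0.05 with camera and a preset correlation, with filled red points for genes past an adjusted p of 0.05, open points for the rest and a bar at the list median. Medians ran from -0.97 for the cell cycle to 1.73 for the glucocorticoid response. All 15 had an adjusted p of at least 0.282 with camera and an estimated correlation, a test on 2 residual degrees of freedom.

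Lists of xenobiotic metabolism, lipoproteins, fatty acid oxidation and heat shock proteins passed with camera, as higher, but had adjusted p = 0.298, adjusted p = 0.349, adjusted p = 0.589 and adjusted p = 0.498 with an estimated correlation. Of 30 xenobiotic metabolism genes 2 rose in both counts and 28 did not pass over all genes (median 0.25, camera adjusted p = 3.8e-09). These were Alas1, which encodes the rate-limiting enzyme of haem synthesis, at 2.10 (SE 0.27, adjusted p = 0.00884), and Cyp2b10, a cytochrome P450 gene, at 1.71 (SE 0.25, adjusted p = 0.0178). Of 19 lipoprotein genes 2 rose in both counts and 17 did not pass over all genes (median 0.15, camera adjusted p = 0.000143). These were Apoa4, an apolipoprotein gene, at 1.72 (SE 0.20, adjusted p = 0.00376), and Angptl4, which encodes an inhibitor of lipoprotein lipase, at 1.84 (SE 0.32, adjusted p = 0.0490). None of the 26 fatty acid oxidation genes passed in either count (median 0.13, camera adjusted p = 0.0255). In that list Cyp4a14, a fatty acid hydroxylase gene, was at 2.78 (SE 1.13, adjusted p = 0.958, with the block 4.7e-57), Pdk4 at 0.67 (SE 0.46, adjusted p = 1.00) and Cpt1a at 0.17 (SE 0.29, adjusted p = 1.00). None of the 14 heat shock genes passed over all genes, and 1 rose adjusted over the list alone, Hspb8, at 0.80 (SE 0.21, adjusted p = 0.341, with the block 5.7e-05; list median 0.32, camera adjusted p = 0.00329). Other probe sets of Hspb8 were at 0.92 and 0.02 (with the block 7.0e-05 and 0.988). Without control pool 2 the adjusted p was 0.0891 for Alas1, 0.343 for Cyp2b10, 0.0682 for Apoa4 and 0.0700 for Angptl4, and 0.536 and 0.645 for the fatty acid oxidation and heat shock lists. Without control pool 1 it was 0.127 for Cyp2b10, 0.104 for Apoa4 and 0.360 for Angptl4, and without stressed pool 1 it was 0.965 and 0.218 for those 2 lists. After quantile normalization the fatty acid oxidation list had an adjusted p of 0.262.

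The other 17 lists did not pass with camera. The lowest adjusted p was 0.0571 for antioxidant genes, where Mt1 and Mt2 were the 2 of 16 that rose (0.00962 with the block), and the male-biased liver genes had 0.101 (0.0217 with the block). With the block these 2 lists had adjusted p = 0.584 and adjusted p = 0.673 with an estimated correlation. The female-biased liver genes (0.101), growth hormone and IGF axis (0.101), cholesterol synthesis (0.135), glycolysis (0.138), bile acids (0.138), circadian clock (0.144) and oxidative phosphorylation (0.177) followed. The lists of sinusoidal endothelium (0.391), stellate cells (0.391), ribosomal proteins (0.472), lipogenesis (0.628), complement and coagulation (0.669), endoplasmic reticulum stress (0.669), hepatocytes (0.769) and neutrophils (0.769) lay above these. Among single genes of these lists, Cyp7a1, the rate-limiting enzyme of classical bile acid synthesis, was at 0.45 (SE 0.22), Sqle, the squalene epoxidase gene, at 0.33 (SE 0.28) and Fasn, the fatty acid synthase gene, at -0.16 (SE 0.27), each with an adjusted p of 1.00. Median, mean and test differed in sign for bile acids (median 0.16, mean -0.01, tested as higher), lipogenesis (0.03, -0.09, tested as lower), female-biased genes (-0.05, 0.24, tested as higher), complement and coagulation (0.03, -0.01, tested as higher) and hepatocytes (-0.02, 0.01, tested as higher).

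The 2 experiments shared no pool, so their stress effects could be set side by side. Saa2 rose alike in both, by 4.97 and 4.89, as did Pck1, by 1.75 and 1.75, and Srebf1 was at -1.44 and -1.42. All 57 changed probe sets had the same sign in both experiments, and their changes correlated across probe sets with r = 0.848, but they were selected by a test on the same pools that favours probe sets alike in both experiments. Across all 13575 probe sets the correlation was r = 0.170 (Spearman's rho 0.132), and probe sets are not independent replicates. It was r = 0.511 over the 6787 brighter and r = 0.0722 over the 6788 dimmer probe sets. The interaction of experiment and stress was tested with limma on the spread between the technical arrays of a pool, so it compares these pools and not the conditions. It passed for 3 probe sets. Mt2 rose by 5.06 in experiment 1 and 2.94 in experiment 2 (adjusted p of the difference = 0.00439), and Mt1 by 3.53 and 1.97 (0.00439). Fabp5, which encodes a fatty acid-binding protein, was at -0.49 and -3.45 (0.0159). Its comparison over both experiments had an adjusted p of 0.379, and 1.5e-12 with the block.

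**Figure D3:**
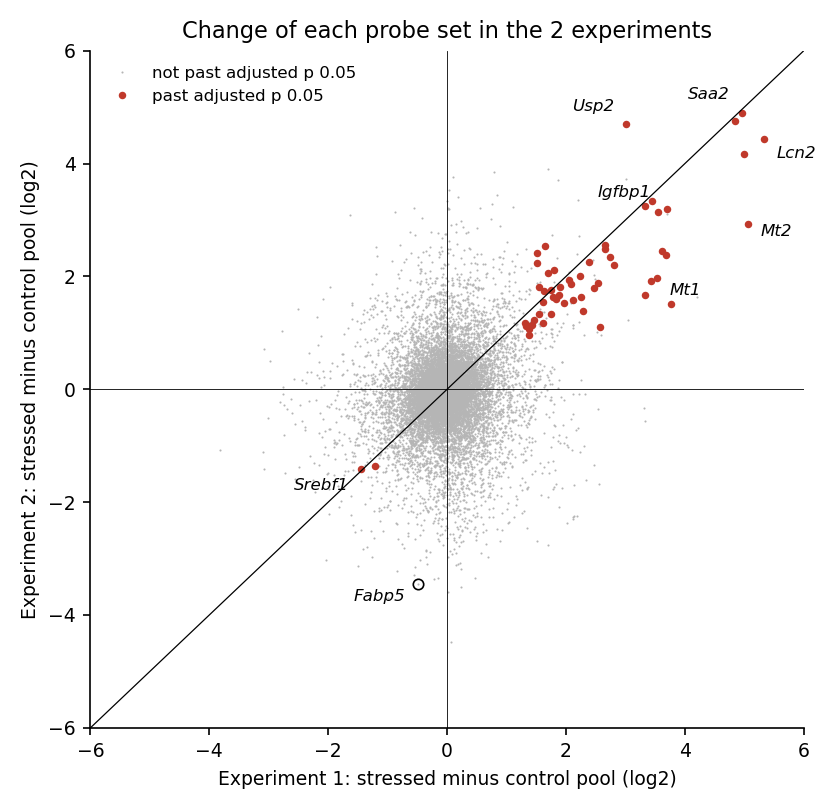
Stressed minus control log2 change of each probe set in experiment 1 (horizontal axis) and experiment 2 (vertical axis), with the 57 probe sets past an adjusted p of 0.05 in red, Fabp5 as an open circle and a line of equal change. Over all 13575 probe sets r was 0.170, and the red probe sets were selected by a test that favours equal change in both experiments, with Mt1 and Mt2 under the line.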

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

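All tests of explanations given here were chosen only after the results were seen, and the one on compressed signals was replaced and its bound revised after a first value had been seen (0.886 over the 55 other changed probe sets, which were selected for change in both experiments), while the interaction test of the 2 experiments was fixed in advance.

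The stress effect differed between the 2 experiments in 3 probe sets, by a test on the spread between technical arrays, which compares these pools and not the conditions. The difference between experiment 1 and experiment 2 was 2.12 (SE 0.24) for Mt2, 1.56 (SE 0.18) for Mt1 and 2.96 (SE 0.39) for Fabp5. The second Fabp5 probe set was at -0.41 and -2.15 in the 2 experiments, with an adjusted p of the difference of 0.0831. The arrays of the 2 experiments also differed in the ratio of 3' to 5' beta-actin signal. Its bearing on the differences in stress effect was not tested.

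The smaller metallothionein rises in experiment 2 were weighed against a general compression of its signals and against a higher baseline in its control pool. The ratio of the experiment 2 to the experiment 1 change was 0.580 for Mt2 and 0.557 for Mt1. Its median was 0.691 over 232 other probe sets picked in experiment 1, a choice that lowers it, and 1.07 over 200 picked in experiment 2, a choice that raises it (95% bootstrap intervals over probe sets, not pools, 0.639 to 0.751 and 0.958 to 1.20). These medians argue against a compression common to all probe sets that is as strong as the Mt1 and Mt2 ratios. Mt1 and Mt2 were picked for a difference between the experiments, which lowers their ratios, and an interval of a median does not give the spread of single probe sets. Whether a weaker compression is a part or the whole of the cause therefore stays open. Of the difference in change, 86.5% for Mt2 and 80.3% for Mt1 lay between the control pools, whose Mt2 signals were 135 and 484 and Mt1 signals 825 and 1967, while the stressed pools had 4520 and 3708 for Mt2 and 9512 and 7687 for Mt1. A higher metallothionein level in the control mice of experiment 2 is a candidate explanation. That share was first computed as a test of a signal ceiling, but a ceiling common to all probe sets is argued against by the highest signals on the stressed arrays, from 23140 to 25820.

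Of the 64 control probe sets, which the comparison left out, 50 lay above the filter, and 2 of these had all 4 stressed arrays above all 4 control arrays. If the 4 pools were exchangeable, both stressed pools would lie above both control pools in 16.7% of probe sets, or 8.33 of 50, and all of their arrays less often. They are not exchangeable for spiked-in transcripts such as Thr, whose signals differed between the experiments. Many control probe sets also share a transcript with others. The count of 2 therefore cannot be weighed against 8.33. The 3' probe set of Gapdh was higher by 0.35, and a middle probe set of pyruvate carboxylase by 0.50. After quantile normalization they were higher by 0.25 and 0.48 and after median centring by 0.44 and 0.59, but the Gapdh arrays of the groups then overlapped. No outlying sample was sought by the gap within a group, since each group holds 2 pools.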

How the results depend on the processing

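No result reversed its direction past the threshold under any alternative. The count of 57 changed probe sets became 0 without the mean-variance trend, where fewer prior degrees of freedom (2.82) held the variances, 460 with the replicate block (pairing by experiment), 137 with all 8 arrays and the pool as a random block, and 13 to 161 with 1 pool left out. Elsewhere it ran from 40 to 69. The 15 lists became 0 with an estimated inter-gene correlation, and 0 with the replicate block and that estimate together. These 2 versions have 2 and 1 residual degrees of freedom and so little power. Elsewhere 12 to 20 passed, 13 to 20 with 1 pool left out. With camera, the 15 lists also passed with the block, as did the antioxidant and male-biased lists, and the block ended no call of a named gene. Among the genes named by rule, besides those given with it, the block added Gpt2, Cth, Plk3, Hspa8, Cyp3a13, Scarb1, Acot1 and Vnn1, and it changed no other call of these genes. Vnn1 was at 0.03 in experiment 1 and -1.58 in experiment 2, and Acot1 at 1.485 and 0.17. The others were higher in both. With infinite prior degrees of freedom a probe set's own disagreement between experiments does not enter its p-value, so passing with the block does not show agreement. Among others outside the rule, H2-Eb1 (limma adjusted p with the block 0.0448) and the brightest Saa4 probe set (2.0e-20) also passed with the block. The correlation of 0.170 between experiments became 0.296 with 32 added to the signal, 0.0567 with no filter, 0.397 with a filter at the 60th percentile, 0.0967 with technical array 1 alone and 0.0908 with technical array 2 alone. Over the 6788 dimmer probe sets it was 0.0722, against 0.511 over the 6787 brighter ones. The 3 interactions became 16 with 32 added and 9 with the filter at the 60th percentile. Beyond the fixed filter and number of arrays, the cause of these moves was not tested. With control pool 2 by its first array, chosen after seeing the data, 48 probe sets and 14 lists passed. For single named genes, 1013 values under the alternatives kept their side of the threshold, 73 gained it and 73 lost it, and for single lists 471, 24 and 46 did.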

Other observations

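All tests of explanations in this part were chosen only after the results were seen, as were the genes of the next paragraph, and the bounds of the tests on the immune lists and on the size of falls were revised after their values had been seen.

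Beyond the genes named by rule, a further 20 genes changed, all of them higher in stressed liver. Pim3, which encodes a serine/threonine kinase, rose by 2.54 (SE 0.24, limma adjusted p = 0.00149), Plin5, which encodes a lipid droplet coat protein, by 2.50 (SE 0.27, adjusted p = 0.00310), and Il1r1, the interleukin 1 receptor gene, by 2.49 (SE 0.42, adjusted p = 0.0359). All 3 probe sets of Rgs16, which encodes a regulator of G protein signalling, rose, by 2.13 to 2.21. Both probe sets of Herpud1, a gene of the endoplasmic reticulum stress response, rose by 1.97 and 1.78, while 14 of the 19 measured genes of that list had a negative change. Cebpb, which encodes a transcription factor of the acute-phase response, rose by 1.73 (SE 0.22, adjusted p = 0.00698). The cytochrome P450 genes Cyp39a1 and Cyp17a1 rose by 1.96 and 1.88. Of all 57 changed probe sets, 14 passed without control pool 1 and 12 without control pool 2.

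Of the 57 changed probe sets 55 were higher, whereas all 1649 probe sets whose arrays separated in both experiments held 722 rises and 927 falls (1027 and 572 after median centring). Were all arrays exchangeable, 377 probe sets would separate by chance in each direction. By chance both stressed pools lie above their control pools in 25% of probe sets, but that is a looser rule than separate arrays. Arrays of a pool are not independent, so neither value is the number expected by chance. The imbalance was not confined to dim probe sets, since 96.3% of the 54 calls above the median level were higher. But these were 54 of the 57 calls, so the share could hardly differ, and loss of falls among dim probe sets stays open. Quantile normalization did not remove the imbalance, since 93.5% of its 46 calls were higher. But 45 of the 46 were among the 57 calls, so the share could hardly differ, and a part of array scaling stays open. Whether falls were smaller stays open, since the 57th largest rise exceeded the 57th largest fall by 0.63 among probe sets above the median level whose arrays separated in both experiments, but most of these rises were the calls themselves. The imbalance was smaller with the replicate block (289 higher and 171 lower, 62.8% higher), without stressed pool 2 (112 and 49, 69.6%), without stressed pool 1 (64 and 21, 75.3%) and with the pool as a random block (112 and 25, 81.8%), while the 15 and 13 calls without control pool 1 or 2 were all higher. Of the 3 ways to split the 4 pools 2 and 2, only 1 gave as many changed probe sets, the real one with 57, the highest other being 0 with limma (1635 at an unadjusted p under 0.05 for the split by experiment and 135 for the other), and 3 splits are too few for a share under 0.05.

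The downward shift of the interferon and antigen presentation lists was weighed against dim signals and fewer immune cells. Dim signals are argued against for the interferon list, whose 13 members above the median level were all negative with a median of -0.47 (median SE 0.26). They stay open for the antigen presentation list, whose 7 such members had a median of -0.14 (median SE 0.22). Among the 7, the MHC class II pathway genes H2-Aa, Cd74 and H2-Eb1 were at -1.20, -0.89 and -0.83. The class I pathway genes H2-K1, H2-D1, Tapbp and B2m were at -0.09, -0.14, -0.09 and 0.06. That median thus mixes the MHC classes and cannot decide on dim signals. Fewer Kupffer cells cannot be told apart from a change within cells, since each list met only 1 of the 2 bounds set against it: the antigen presentation median minus the Kupffer median was -0.55, beyond the median SE of its members (0.32) but with a 95% bootstrap interval over genes, not pools, of -0.94 to 0.18, and for the interferon list it was -0.20, with an interval of -0.67 to -0.11 but within the median SE (0.31). Fewer lymphocytes stay open too, since the 7 T, B and NK cell markers above the filter had a median of -0.35 with a median SE of 0.69, and 5 of them were negative. Repeated stress itself and the difference in housing were not separated by the design.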
